A study of Homo sapiens with 13 samples.

How the data were processed

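The data are RNA sequencing counts from HuT78 cells, with 13 libraries in 4 treatment groups: chaetocin (replicates 1 to 4), F5446 (2 to 4), romidepsin (1 to 4) and DMSO (1 and 4). Per the labels, RNA was extracted with a column kit with DNase treatment and made into libraries with a kit for human RNA that includes degraded RNA. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.20.0.422, adapters were trimmed with cutadapt 1.8.1 and reads were counted per gene with HTSeq 0.6.1 on hg19. The aligner, the strand setting and the annotation release are not given in the sources used here, so antisense and overlapping genes cannot be separated and no positions are given. The deposited values are raw counts, whole numbers for 45744 genes, and all sample columns were used. The treatment tags of the F5446 libraries carry code names that end in different digits, while their titles all give F5446; the titles were used.

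Genes were kept by the edgeR rule for enough counts given the group sizes, which left 17252. All 13 libraries were fitted together with group as the only term, using edgeR 4.0.16 in R 4.3.3 with TMM normalization and the robust quasi-likelihood test. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison over all genes, with a threshold of 0.05 and no minimum fold. Each compound was compared with DMSO and the compounds with each other. Log2 CPM for scores and principal components used a prior count of 2, and confidence intervals are at 95%. Library totals ran from 19901052 to 30816188 counts; intervals reflect spread between libraries and counting error together. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples.

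The gene lists (39, of which 38 had at least 3 tested members) were written from general knowledge. They were tested with camera from limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over all lists and the comparisons against DMSO together, or over the lists within each comparison of compounds. Each was also tested with an estimated correlation and with fry, and members were counted after adjustment over all genes and over the list alone. Genes named in the text were chosen by rule: among called genes with a mean of at least 5 CPM whose libraries did not overlap between the groups, those with the largest rises and falls. Where none was called, the 5 with the smallest p were taken, with a set of genes of the drug targets and of Sézary cells and the top members of lists that held a called gene. Some genes that the rule names are not reported here. The comparisons with their test, the lists and the naming rule were fixed before the data were examined; tests of explanations and the additions named here came partly later.

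Alternatives were DESeq2 1.42.0, limma-voom, other scalings, no filter, a filter at a mean of 5 CPM, a non-robust fit, a minimum log2 fold of 0.5, a fit of the 2 groups compared, a replicate block and each library left out in turn. A fit that left 1 DMSO library assumed that it varies like the other groups. A term for replicate numbers 1 and 2 against 3 and 4, values within these sets, correlations over genes of at least 10 CPM and the omission of mitochondrially encoded genes were added after the data were seen. The pipeline was tested on simulated data with 200 changed genes and on 20 simulations of unchanged groups. GC content and transcript length came from another annotation release and served only to test for bias. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.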

Results

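RNA sequencing measured gene expression in HuT78, a cell line derived from Sézary syndrome, the leukemic form of cutaneous T cell lymphoma. The cells were treated for 72 h with chaetocin at 10 nM (4 libraries), F5446 at 10 nM (3 libraries), romidepsin at 1 µM (4 libraries) or the vehicle DMSO (2 libraries). Chaetocin is a fungal metabolite that inhibits SUV39H1-type histone H3 lysine 9 methyltransferases, and F5446 is a code-named inhibitor of SUV39H1. Romidepsin is a histone deacetylase inhibitor used in cutaneous T cell lymphoma. The libraries held 23024895, 30816188, 23367823 and 25493139 counts for chaetocin replicates 1 to 4. They held 29002774, 26694459 and 19951198 for F5446 replicates 2, 3 and 4. Romidepsin replicates 1 to 4 had 21948240, 19901052, 30494499 and 21556874, and DMSO replicates 1 and 4 had 21104305 and 20128474. Of 45744 genes in the deposited table, 17252 had enough counts to be tested. Values are CPM, counts scaled to the normalized library size, with the SD between libraries, and a gene or list is named as called where its adjusted p was under 0.05.

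On the first principal component the libraries parted by replicate number and not by treatment. It held 17.8% of the variance and set chaetocin replicate 3 apart at 112.7, where the other 12 libraries lay between -36.7 and 18.7. Every library numbered 1 or 2 had a negative score on it, and every library numbered 3 or 4 a positive one. Mitochondrially encoded genes took 8.49 to 12.4% of the counts in libraries numbered 1 or 2. They took 5.03 to 8.64% in those numbered 3 or 4, except chaetocin replicate 3 with 15.4%. Values within these sets of replicate numbers, a division chosen after the data were seen, are given for selected results and for each called list whose median differed in sign between them. Each set holds a single DMSO library, and numbers 1 and 2 hold a single F5446 library. Within-set values that use these groups therefore rest on single libraries, and shared or opposite signs among them are weak evidence.

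**Figure D1:**
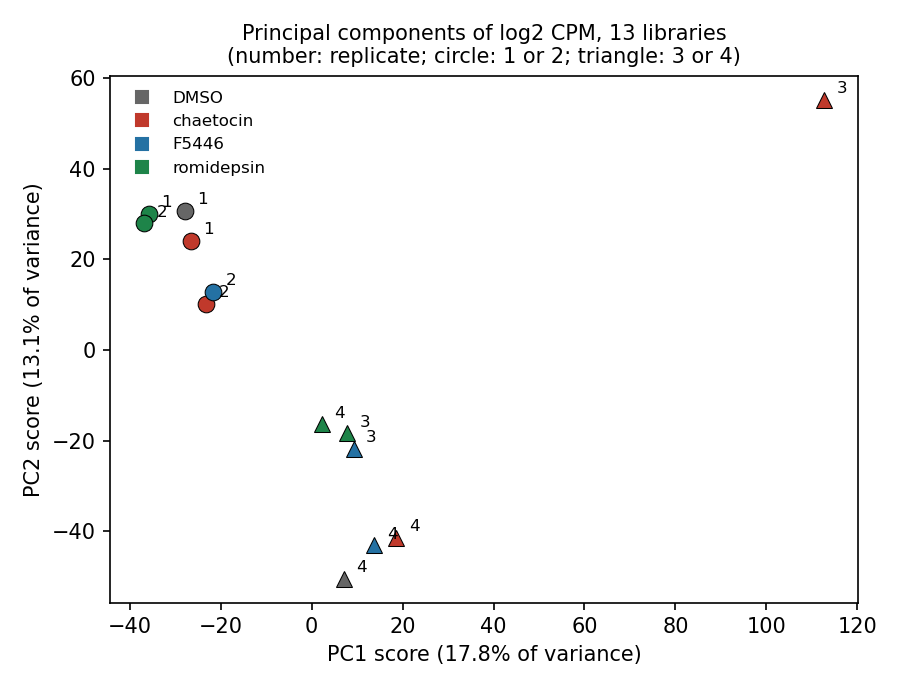
Scores of the 13 libraries on the first (17.8% of variance) and second (13.1%) principal components of log2 CPM, with 1 point per library, colored by treatment and labelled by replicate number. Chaetocin replicate 3 lies at 112.7 on the first component, and libraries numbered 1 or 2 lie on its negative side.

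The comparison of chaetocin with DMSO asks which transcripts the methyltransferase inhibitor changes. Among the 5 genes with the smallest p-values were SLFN5, ATF5, GPR155 and OAS2, and none of the 5 was called. SLFN5, an interferon-inducible Schlafen family member, was at 177.5 ± 28.6 CPM with chaetocin (SD, n = 4) and 324.6 ± 6.78 with DMSO (SD, n = 2). Its log2 fold change was -0.87 (95% CI -1.18 to -0.56, edgeR adjusted p = 0.131), and it was -0.76 in replicate numbers 1 and 2 and -1.01 in 3 and 4. ATF5, a transcription factor of the cellular stress response, had a log2 fold change of 1.47 (95% CI 0.90 to 2.04, edgeR adjusted p = 0.299) with 276.5 ± 86.1 against 100 ± 0.897 CPM. GPR155 and OAS2, an interferon-induced oligoadenylate synthetase, were at -1.13 and -0.62 on the log2 scale. SUV39H1 itself, the methyltransferase gene, was at 38.2 ± 5.68 against 37.7 ± 4.54 CPM (log2 fold change 0.02, 95% CI -0.35 to 0.39). GATA3, a T helper transcription factor often high in Sézary cells, was at 1012 ± 476.9 against 643.2 ± 83.8 CPM (log2 fold change 0.65, 95% CI -0.14 to 1.45). By edgeR, 0 of 17252 genes were called, with 703 at an unadjusted p under 0.05 where 863 would be so by chance. DESeq2 called 10 (5 higher and 5 lower) and limma-voom 0. The edgeR count was 1 without chaetocin replicate 4 and 2 without DMSO replicate 4. With a term for replicate numbers 1 and 2 against 3 and 4, edgeR called 7 genes, all lower with chaetocin, among them SLFN5 (adjusted p = 0.000999), CMPK2, GBP1, STX3, ITGA6 and OAS2. This term was chosen after the data were seen.

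Among gene groups, 27 of 40 interferon-stimulated genes were lower with chaetocin than with DMSO (median log2 fold change -0.24, mean -0.04), with 0 called over all genes and 2 lower adjusted over the list alone, OAS2 among them. The group was called by camera with its preset correlation (adjusted p = 0.00864), but not with an estimated correlation (adjusted p = 0.983) or without DMSO replicate 1 (median -0.02, camera adjusted p = 0.582), and its median was -0.12 without chaetocin replicate 3. Within replicate numbers 1 and 2 the median was -0.26, and within 3 and 4 it was -0.08. Cytotoxic effector genes, which T cells and natural killer cells use to kill targets, had a median of -0.18 and 9 of 13 members lower (camera adjusted p = 0.000895, 0.666 with an estimated correlation). GZMA, a granzyme, at 6.45 against 15.4 CPM, and IFNG, the interferon gamma gene, at 0.402 against 3.0 CPM, were lower adjusted over the list alone. The cytotoxic median was -0.47 in replicate numbers 1 and 2 and 0.04 in 3 and 4, and it was -0.10 without chaetocin replicate 1, -0.28 without replicate 2 and -0.39 without replicate 4. The 32 genes of the integrated stress and unfolded protein response had a median of 0.10, with 1 higher adjusted over the list alone, ATF5 (camera adjusted p = 0.0192, 0.983 with an estimated correlation). That call was lost without chaetocin replicate 1 (0.119), chaetocin replicate 3 (0.113) or DMSO replicate 1 (0.502), and without DMSO replicate 4 the median was 0.18. Replication-dependent histones, whose near-identical copies make single values uncertain, were above 0 in 51 of 61 (median 0.16, camera adjusted p = 8.11e-05), and not called without DMSO replicate 1 (0.582), with a median of 0.29 without DMSO replicate 4. Nuclear-encoded oxidative phosphorylation genes (71 of 80 above 0, median 0.18, camera adjusted p = 3.36e-05) and ribosomal proteins (67 of 82, median 0.13, camera adjusted p = 0.000895) were also called. These last 3 groups had an adjusted p of 0.983 with an estimated correlation. In replicate numbers 1 and 2 the medians were -0.14 for oxidative phosphorylation and -0.18 for ribosomal proteins, and in 3 and 4 they were 0.51 and 0.40. Without chaetocin replicate 3 neither was called (camera adjusted p = 0.266 and 0.776), nor without DMSO replicate 4 (0.750 and 0.831), and ribosomal proteins were not called without chaetocin replicate 4 (0.0807). Without chaetocin replicate 1 or DMSO replicate 1 the medians were higher, at 0.27 and 0.36 for oxidative phosphorylation and 0.24 and 0.25 for ribosomal proteins, which were at 0.20 without chaetocin replicate 2. The 25 genes of the histone H3 lysine 9 methylation machinery had a median of 0.05 and were not called.

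The comparison of F5446 with DMSO asks which transcripts the SUV39H1 inhibitor changes. The 5 genes with the smallest p-values were C6orf226, ALG9, CHAF1A, SYNGR2 and CGB2, and none was called. C6orf226, an uncharacterized open reading frame, was at 6.94 ± 0.182 CPM with F5446 (SD, n = 3) and 1.52 ± 0.161 with DMSO (SD, n = 2), a log2 fold change of 2.19 (95% CI 1.29 to 3.09, edgeR adjusted p = 0.880). It was 1.99 in replicate numbers 1 and 2, with a single library per group, and 2.26 in 3 and 4. CHAF1A, which encodes a subunit of the chromatin assembly factor of replicating cells, was at 123.4 ± 6.90 against 187.8 ± 26.4 CPM (log2 fold change -0.61). ALG9, an enzyme of N-glycan assembly, was at -1.15 and SYNGR2 at 0.52 on the log2 scale. CGB2, a chorionic gonadotropin gene with near-identical copies, was at 0.537 CPM with F5446 and had no counts in either DMSO library. SUV39H1 had a log2 fold change of 0.18 (95% CI -0.21 to 0.57), and FAS, the death receptor gene, one of 0.16 (95% CI -0.41 to 0.73). By edgeR, 0 genes were called, with 428 at an unadjusted p under 0.05; DESeq2 called 1, which was higher, and limma-voom 0.

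Among gene groups, mitosis genes were higher with F5446 in 31 of 34 members (median 0.18, camera adjusted p = 0.000895), and stress-response genes in 26 of 32 (median 0.18, camera adjusted p = 0.0135). Ribosomal proteins were higher in 62 of 82 (median 0.11, camera adjusted p = 0.00844), and the 13 mitochondrially encoded genes were all lower (median -0.47, camera adjusted p = 3.94e-05). With an estimated correlation the adjusted p was 0.983 for each of these 4 groups, and 0 of their members were called over all genes or adjusted over the list alone. The stress-response median was -0.02 in replicate numbers 1 and 2 and 0.22 in 3 and 4, so its sign was not shared. The mitosis medians were 0.10 and 0.15, those of ribosomal proteins 0.21 and 0.12, and those of mitochondrially encoded genes -0.46 and -0.26. Mitosis, stress-response and mitochondrially encoded genes lost their calls without F5446 replicate 3 (camera adjusted p = 0.114, 0.523 and 0.0732) or DMSO replicate 1 (0.529, 0.374 and 0.780). Ribosomal proteins lost theirs without F5446 replicate 2 (0.965) or DMSO replicate 4 (0.975). The mitochondrially encoded median was 0.04 without DMSO replicate 1, -0.87 without DMSO replicate 4 and -0.82 without F5446 replicate 2, the mitosis median 0.31 without DMSO replicate 4, and the stress-response median 0.05 without F5446 replicate 3. The ribosomal protein median was 0.17 without F5446 replicate 3 and 0.21 without DMSO replicate 1. With replicate numbers as a block it was -0.053, opposite in sign and not called (camera adjusted p = 0.5485), and 2 of the 4 groups kept their calls. The count of 4 groups was 2 without F5446 replicate 3 and 9 without DMSO replicate 4. The methylation machinery had a median of 0.01.

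The comparison of romidepsin with DMSO asks which transcripts the deacetylase inhibitor changes. The 5 genes with the smallest p-values were CKB, CAPN6, TESC, PALLD and HLA-DRB1, all with higher means under romidepsin, and none was called. CKB, the brain-type creatine kinase gene, was at 73.8 ± 7.55 CPM with romidepsin (SD, n = 4) and 33.0 ± 4.87 with DMSO (SD, n = 2), a log2 fold change of 1.16 (95% CI 0.73 to 1.60, edgeR adjusted p = 0.255). It was 0.92 in replicate numbers 1 and 2 and 1.41 in 3 and 4, and with a term for them edgeR called it (adjusted p = 0.0182). CAPN6, a calpain-family gene, was at 81.0 ± 10.1 against 40.5 ± 2.59 CPM (log2 fold change 1.00, 95% CI 0.55 to 1.45). TESC, PALLD, which encodes the actin-associated protein palladin, and HLA-DRB1, a class II antigen-presenting gene with near-identical relatives, were at 1.30, 0.57 and 0.72. FASLG, the ligand of the FAS death receptor, was at 13.9 ± 1.58 against 7.04 ± 2.10 CPM (log2 fold change 0.98, 95% CI 0.29 to 1.67, edgeR adjusted p = 1). By edgeR, 0 genes were called, with 487 at an unadjusted p under 0.05; DESeq2 called 1, which was higher, and limma-voom 0. CDKN1A, a cell-cycle inhibitor gene that deacetylase inhibitors commonly induce, was at 3.34 ± 1.02 against 2.34 ± 1.20 CPM (log2 fold change 0.52, 95% CI -0.73 to 1.76). The 15 tested genes commonly induced by such inhibitors had a median log2 fold change of 0.05 with romidepsin (mean 0.11), -0.27 with chaetocin (mean -0.03) and 0.09 with F5446 (mean 0.24), and the list was called in none of these comparisons. HDAC1, a target of romidepsin, had a log2 fold change of 0.23 (95% CI -0.06 to 0.52), and the 18 histone deacetylases and sirtuins a median of -0.13.

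Among gene groups, antigen presentation genes were higher with romidepsin than with DMSO in 23 of 28 members (median 0.17, camera adjusted p = 3.36e-05). Over all genes 0 of them were called, and 1 was higher adjusted over the list alone, HLA-DRB1. The median was 0.09 in replicate numbers 1 and 2 and 0.20 in 3 and 4, the adjusted p was 0.329 with an estimated correlation, and the call was lost without DMSO replicate 4 (camera adjusted p = 0.0753). Glycolysis and hypoxia genes were lower in 25 of 30 (median -0.12, camera adjusted p = 0.0177), but not called with an estimated correlation (adjusted p = 0.983). They were also not called without romidepsin replicate 1 (0.291), romidepsin replicate 2 (0.326) or DMSO replicate 4 (0.618, median 0.16), and the median was -0.30 without romidepsin replicate 3 and -0.40 without DMSO replicate 1. The count of 2 groups was 4 without romidepsin replicate 3 or 4, 6 without DMSO replicate 1 and 7 without DMSO replicate 4.

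Chaetocin and F5446 were given at the same nominal dose and time, so their direct comparison asks where these treatments differ. Inhibition of their target was not measured here, so an equal dose does not show an equal effect on it. Cytotoxic effector and antigen presentation genes were lower with chaetocin, and no single gene was called. Cytotoxic effector genes were lower in 12 of 13 members (median log2 difference -0.29), and were called with the preset correlation (camera adjusted p = 1.18e-06) and with an estimated one (0.0421). GZMA at 6.45 ± 1.73 against 14.6 ± 4.19 CPM and GNLY, the granulysin gene, at 0.919 against 3.04 CPM were lower adjusted over the list alone, and 0 were called over all genes. The cytotoxic median was -0.57 in replicate numbers 1 and 2 and -0.19 in 3 and 4, and it was -0.44 without chaetocin replicate 4. Antigen presentation genes were lower in 21 of 28 (median -0.21, camera adjusted p = 2.08e-06, 0.0421 with an estimated correlation), with medians of -0.22 and -0.16 within the sets of replicate numbers. B2M, the light chain of class I molecules, was lower adjusted over the list alone, at 1005 ± 195.7 against 1586 ± 342.3 CPM. The 5 genes with the smallest p-values were ITGB7, SLFN5, STX3, CDYL2 and GZMA, all with lower means under chaetocin. ITGB7, an integrin gene of lymphocyte homing, was at 32.4 ± 5.16 against 54.4 ± 4.17 CPM (log2 difference -0.75, 95% CI -1.05 to -0.44, edgeR adjusted p = 0.397). SLFN5 differed by -0.68 (95% CI -0.96 to -0.40), STX3 by -0.88 (-1.28 to -0.48), CDYL2 by -0.82 (-1.20 to -0.43) and GZMA by -1.17 (-1.74 to -0.60). By edgeR, 0 genes were called, with 587 at an unadjusted p under 0.05; DESeq2 called 2, both lower, and limma-voom 0. With the term for replicate numbers 1 and 2 against 3 and 4, edgeR called 5 genes, all lower with chaetocin, among them STX3 (log2 difference -0.84, adjusted p = 0.00626), SLFN5, ITGB7 and RNF144A.

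A further 8 groups differed between chaetocin and F5446 by camera with the preset correlation only. The 13 mitochondrially encoded genes were all higher with chaetocin (median 0.78, camera adjusted p = 2.10e-11, 0.483 with an estimated correlation), and their median was 0.42 without chaetocin replicate 3. Ribosome biogenesis and MYC target genes were higher in 25 of 31 (median 0.17, camera adjusted p = 0.000164, 0.629 with an estimated correlation). Mitosis genes were lower in 29 of 34 (median -0.12, camera adjusted p = 0.00216, 0.778 with an estimated correlation). Histones, oxidative phosphorylation and fibroblast markers (8 tested genes) had medians of 0.11, 0.09 and 0.37, and metallothioneins (4 tested genes) and glycolysis genes medians of -0.76 and -0.19. Their adjusted p lay between 0.167 and 0.887 with an estimated correlation. In replicate numbers 1 and 2 the oxidative phosphorylation median was -0.31 and the glycolysis median 0.13, and in 3 and 4 they were 0.44 and -0.18, opposite in sign. The mitochondrially encoded medians were 0.23 and 0.91, and the other 5 groups kept 1 sign in both sets. Each of these groups except the mitochondrially encoded genes lost its call when single libraries were left out. Without chaetocin replicate 1 this held for ribosome biogenesis (median 0.08, camera adjusted p = 0.0538), mitosis (-0.08, 0.149), histones (0.07, 0.0704), metallothioneins (-0.69, 0.0704), glycolysis (-0.10, 0.382) and fibroblast markers (0.09, 0.0704). It also held without chaetocin replicate 2 for mitosis (-0.07, camera adjusted p = 0.0922), metallothioneins (-0.62, 0.104) and glycolysis (-0.07, 0.658). Without chaetocin replicate 3 the calls of histones (0.07, camera adjusted p = 0.106) and oxidative phosphorylation (-0.03, 0.471) were lost, and without replicate 4 that of oxidative phosphorylation (0.08, 0.169). Fibroblast markers lost theirs without F5446 replicate 2 (0.28, camera adjusted p = 0.0592). Mitosis (-0.05, camera adjusted p = 0.238), glycolysis (-0.11, 0.404) and oxidative phosphorylation (0.03, 0.542) did so without F5446 replicate 3. Without F5446 replicate 4 histones (0.09, camera adjusted p = 0.0986), metallothioneins (-0.45, 0.210), glycolysis (0.03, 0.809) and oxidative phosphorylation (0.02, 0.773) did so. The ribosome biogenesis median was 0.10 without F5446 replicate 3 and 0.09 without 4. Without F5446 replicate 2 the medians of mitosis, histones, glycolysis and oxidative phosphorylation were -0.20, 0.17, -0.43 and 0.23. That of oxidative phosphorylation was 0.17 without chaetocin replicate 1, and that of glycolysis -0.35 without chaetocin replicate 4. Without chaetocin replicate 1 the count of 10 groups was 5, and without F5446 replicate 4 it was 6.

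Romidepsin against chaetocin, given at different doses, was the comparison with called genes. With romidepsin 13 genes were higher and 3 lower than with chaetocin (edgeR, 939 genes at an unadjusted p under 0.05), and for each of the 16 all 4 libraries of 1 group lay beyond all 4 of the other. GZMA (ENSG00000145649) was at 21.3 ± 6.54 CPM with romidepsin and 6.45 ± 1.73 with chaetocin (SD, n = 4 each), a log2 difference of 1.72 (95% CI 1.18 to 2.26, edgeR adjusted p = 0.00633). The DMSO mean was 15.4 CPM and the F5446 mean 14.6 CPM. SLAMF7 (ENSG00000026751), a receptor of activated lymphocytes, was at 9.55 ± 4.61 against 2.57 ± 0.616 CPM (1.88, adjusted p = 0.0219 by edgeR). MS4A1 (ENSG00000156738), which encodes CD20, was at 23.8 ± 7.53 against 9.45 ± 1.96 CPM (1.33), and CAPN6 (ENSG00000077274) at 81.0 ± 10.1 against 34.1 ± 10.2 (1.25). Lower with romidepsin were TNFRSF4 (ENSG00000186827), the costimulatory receptor OX40, at 4.16 ± 1.69 against 12.5 ± 1.87 CPM (-1.58), ATF5 (ENSG00000169136) at 98.0 ± 14.9 against 276.5 ± 86.1 (-1.50), and ACTA2 (ENSG00000107796), a smooth muscle actin gene, at 443.9 ± 72.5 against 749 ± 82.8 (-0.75). Further called genes, all higher with romidepsin, were the interferon-inducible GBP2 (1.17) and OAS2 (0.70), ITGB7 (0.94), PRKCB (0.99), CDYL2 (1.06), STX3 (1.00), GPRIN3 (0.96) and FAT4 (2.21), named after their values were seen.

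**Figure D2:**
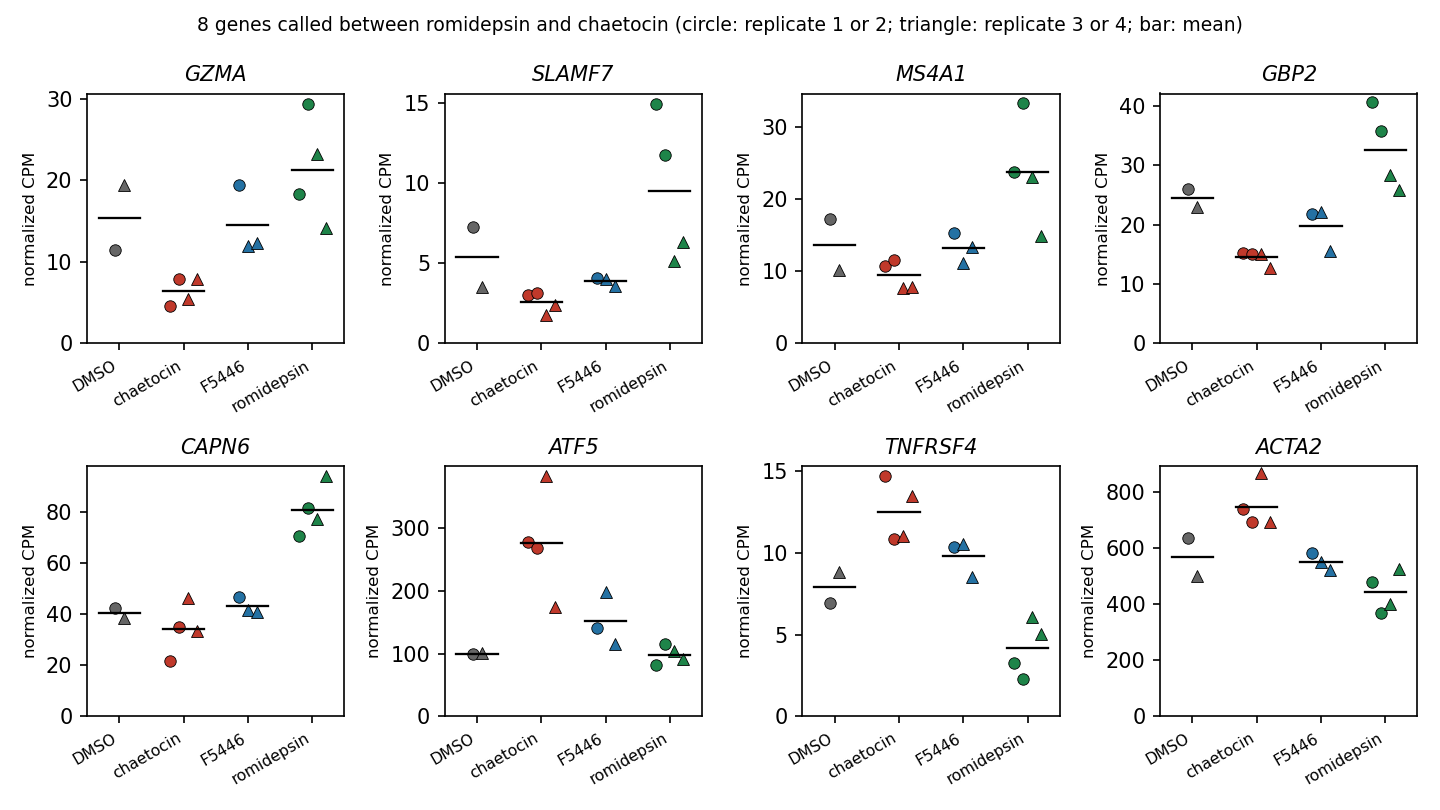
Normalized CPM of 8 genes called between romidepsin and chaetocin, with 1 point per library by treatment (circles for replicate numbers 1 and 2, triangles for 3 and 4) and bars at group means. For GZMA the 4 chaetocin libraries lie between 4.57 and 7.93 CPM and the 4 romidepsin libraries between 14.2 and 29.4 CPM.

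All 16 genes kept their direction within both sets of replicate numbers. This follows from the separation of their libraries and is no further support. GZMA differed by 1.93 in 1 and 2 and 1.46 in 3 and 4, and ATF5 by -1.50 and -1.40. DESeq2 called 62 genes (52 higher and 10 lower), limma-voom 15, and edgeR with the term for replicate numbers 108 (94 higher and 14 lower). All 16 were among the genes called by DESeq2 and with that term, and 13 among those of limma-voom. Tested against a minimum log2 fold of 0.5, 0 genes were called by edgeR, with 257 at an unadjusted p under 0.05. A fit of these 2 groups alone called 7, of which 6 were among the 16. Leaving out single libraries gave between 5 calls (without romidepsin replicate 2) and 22 (without chaetocin replicate 3). CAPN6, ATF5, ITGB7, GBP2 and PRKCB were called without any 1 library. Without romidepsin replicate 2 the calls of CDYL2 (adjusted p = 0.0580) and GZMA (0.0521) were lost by edgeR. ACTA2 was lost without romidepsin replicates 2 or 3, TNFRSF4 without romidepsin replicates 1 or 2, and OAS2 without chaetocin replicate 4 or romidepsin replicate 2, with an edgeR adjusted p of 0.0560 to 0.114. MS4A1 was lost without chaetocin replicates 3 or 4 or romidepsin replicates 1, 2 or 3 (edgeR adjusted p = 0.0560 to 0.158). SLAMF7 was lost without chaetocin replicates 2, 3 or 4 or romidepsin replicates 1 or 2 (edgeR adjusted p = 0.0542 to 0.146). STX3 was lost without any of 5 libraries, chaetocin replicates 1 and 2 and romidepsin replicates 2, 3 and 4 (edgeR adjusted p = 0.0865 to 0.130). GPRIN3 was lost without any of 8 (0.0702 to 0.144) and FAT4 without any of 10 (0.0545 to 0.153); both were called without chaetocin replicate 3 or either DMSO library, and GPRIN3 also without F5446 replicates 2 or 4.

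Among gene groups, antigen presentation genes were higher with romidepsin than with chaetocin in 26 of 28 members (median log2 difference 0.34, camera adjusted p = 5.66e-14). The call held with an estimated correlation (0.00491), the median was 0.27 in replicate numbers 1 and 2 and 0.34 in 3 and 4, and it stayed between 0.27 and 0.36 without any 1 library. Over all genes 0 members were called, and 6 were higher adjusted over the list alone: HLA-B at 700.4 ± 92.0 against 442.5 ± 121.2 CPM, the peptide transporter TAP1, B2M, the immunoproteasome subunit PSMB9, NLRC5 and ERAP2. Counts of HLA genes depend on how reads shared between near-identical genes were assigned. Cytotoxic effector genes were higher in 12 of 13, with CTSW the exception (median 0.46, camera adjusted p = 3.32e-09, 0.0124 with an estimated correlation). GZMA was called over all genes, and 5 were higher adjusted over the list alone: GZMA, FASLG at 13.9 against 6.21 CPM, GNLY at 2.87 against 0.919, GZMK at 24.5 against 13.4 and IFNG at 1.60 against 0.402. The cytotoxic median was 0.65 in replicate numbers 1 and 2 and 0.31 in 3 and 4, and it was 0.23 without chaetocin replicate 1 and 0.29 without chaetocin replicate 2.

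**Figure D3:**
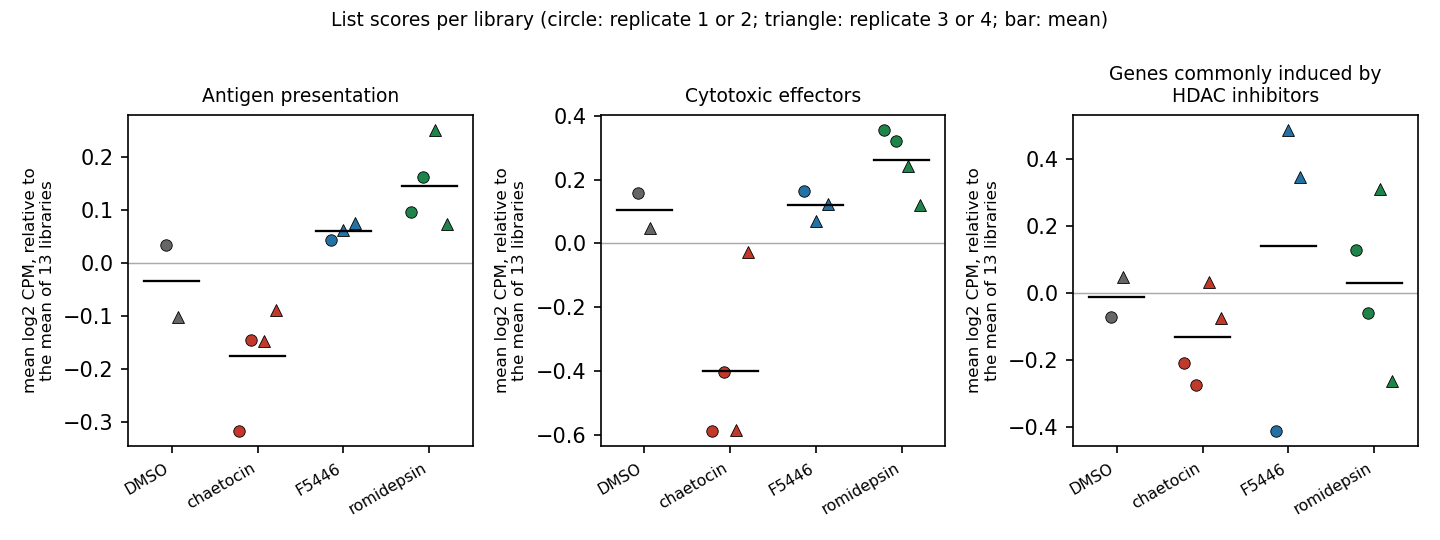
Mean log2 CPM of the members of 3 gene lists (antigen presentation, cytotoxic effectors, genes commonly induced by HDAC inhibitors), relative to the mean of the 13 libraries, with 1 point per library by treatment (circles for replicate numbers 1 and 2, triangles for 3 and 4) and bars at group means. All 4 chaetocin libraries lie below 0 and all 4 romidepsin libraries above 0 for Antigen presentation (-0.32 to -0.09 and 0.07 to 0.25) and for Cytotoxic effectors (-0.59 to -0.03 and 0.12 to 0.36).

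The other 10 groups called between romidepsin and chaetocin were called with the preset correlation only. Interferon-stimulated genes had a median of 0.18 with 25 of 40 above 0 (camera adjusted p = 0.00118, 0.166 with an estimated correlation), and 2 were called over all genes, OAS2 among them. Oxidative phosphorylation genes were lower in 69 of 80 (median -0.20, camera adjusted p = 2.95e-09, 0.465 with an estimated correlation) and ribosomal proteins in 73 of 82 (median -0.17, camera adjusted p = 3.64e-08, 0.505 with an estimated correlation). Thioredoxin, glutathione and NRF2 target genes were lower in 26 of 32 (median -0.14), the stress response had a median of -0.09 with ATF5 and the amino acid transporter gene SLC3A2 lower adjusted over the list alone, and ribosome biogenesis genes had one of -0.10. Histones had a median of -0.13, fibroblast markers (8 tested genes) -0.25, B cell markers (6) 0.35 and monocyte markers (5) 0.58. With an estimated correlation the adjusted p of these groups lay between 0.129 and 0.531. The stress-response median was -0.13 in replicate numbers 1 and 2 and 0.04 in 3 and 4, and that of ribosome biogenesis -0.14 and 0.01, so neither kept its sign. The stress-response call was also lost without chaetocin replicate 3 (median 0.0017, camera adjusted p = 0.0757), romidepsin replicate 2 (0.195) or romidepsin replicate 4 (0.104), and its median was -0.18 without romidepsin replicate 3. The medians of oxidative phosphorylation and ribosomal proteins were -0.08 and -0.07 without chaetocin replicate 3, and that of interferon-stimulated genes 0.10 without romidepsin replicate 1. Without chaetocin replicate 1 the calls of histones (median -0.04, camera adjusted p = 0.304), the stress response (-0.09, 0.133), ribosome biogenesis (-0.03, 0.470) and B cell (0.43), monocyte (0.46) and fibroblast markers (-0.21; 0.133 each) were lost. Histones also lost theirs without chaetocin replicate 3 (-0.04, camera adjusted p = 0.187), romidepsin replicate 2 (-0.07, 0.184) or 4 (-0.07, 0.226). Ribosome biogenesis did so without chaetocin replicate 2 (-0.10, camera adjusted p = 0.0572), romidepsin replicate 3 (-0.06, 0.0858) or 4 (-0.09, 0.0896). The thioredoxin call was lost without romidepsin replicate 2 (-0.09, camera adjusted p = 0.0628), that of monocyte markers without romidepsin replicate 4 (0.48, 0.0896) and that of fibroblast markers without romidepsin replicate 3 (-0.23, 0.0856). The fibroblast median was -0.11 without chaetocin replicate 2, the B cell median 0.16 without chaetocin replicate 4, the stress-response median -0.05 and the ribosomal protein median -0.11 without romidepsin replicate 1. The count of 12 groups was 6 without chaetocin replicate 1 and 18 without chaetocin replicate 3.

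For romidepsin against F5446 edgeR called no gene with group as the only term. The 5 genes with the smallest p-values were CAPN6, CKB, TNFRSF4, GBP2 and LTB, each with an edgeR adjusted p of 1. CAPN6 was at 81.0 ± 10.1 CPM with romidepsin (n = 4) and 43.2 ± 3.02 with F5446 (n = 3), a log2 difference of 0.91 (95% CI 0.52 to 1.29). CKB was at 0.83 (95% CI 0.46 to 1.20), and TNFRSF4, at 4.16 ± 1.69 against 9.83 ± 1.103 CPM, at -1.23 (95% CI -1.81 to -0.66). LTB, the lymphotoxin beta gene, was at 9.10 ± 2.07 against 16.04 ± 2.12 CPM. By edgeR, 0 genes were called, with 424 at an unadjusted p under 0.05, and DESeq2 and limma-voom each called 0. A fit of these 2 groups alone called 2, and a fit without the filter on low counts 6. Among gene groups, T cell activation and cytokine genes were lower with romidepsin in 14 of 22 (median -0.29, camera adjusted p = 0.0316), with TNFRSF4 and LTB lower adjusted over the list alone, and 0.418 with an estimated correlation. Glycolysis and hypoxia genes were lower in 27 of 30 (median -0.25, camera adjusted p = 0.000827, 0.709 with an estimated correlation), but their median was 0.19 in replicate numbers 1 and 2 and -0.28 in 3 and 4. The 13 mitochondrially encoded genes were all higher (median 0.54, camera adjusted p = 9.60e-07, 0.645 with an estimated correlation). The T cell activation call was lost without F5446 replicate 3 (median -0.15, camera adjusted p = 0.288) or 4 (-0.13, 0.0789) or romidepsin replicate 1 (-0.16, 0.150) or 2 (-0.15, 0.132). The glycolysis call was lost without F5446 replicate 3 (-0.17, camera adjusted p = 0.169) or 4 (-0.01, 0.917) or romidepsin replicate 1 (-0.19, 0.0595) or 2 (-0.19, 0.132), its median was -0.48 without F5446 replicate 2, and the mitochondrially encoded median was 0.82 without F5446 replicate 2. A total of 11 groups were called with the preset correlation, 7 of them with the same sign within both sets of replicate numbers, and 0 with an estimated correlation. The others with opposite signs in replicate numbers 1 and 2 and in 3 and 4 were metallothioneins (0.11 and -0.98), ribosomal proteins (-0.39 and 0.03) and oxidative phosphorylation (-0.46 and 0.09). The count was 4 without F5446 replicate 3 and 5 without romidepsin replicate 1 or 2.

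The other 8 groups called between romidepsin and F5446 each lost the call without single libraries. Antigen presentation genes were higher with romidepsin in 19 of 28 (median 0.08, camera adjusted p = 0.0115), with the call lost without F5446 replicate 3 (0.07, 0.0512) or romidepsin replicate 3 (0.07, 0.151) and a median of 0.13 without F5446 replicate 2. Mitosis genes were lower in 27 of 34 (median -0.13, camera adjusted p = 0.0115). That call was lost without F5446 replicate 3 (-0.06, 0.519) or 4 (-0.07, 0.110) or romidepsin replicate 1 (-0.06, 0.290) or 2 (-0.07, 0.146), and the median was -0.22 without F5446 replicate 2 and -0.21 without romidepsin replicate 3. The stress response was lower in 24 of 32 (median -0.08, camera adjusted p = 0.0135), not called without F5446 replicate 3 (-0.01, 0.663) or romidepsin replicate 2 (-0.05, 0.286) or 4 (-0.07, 0.0739), and at -0.19 without F5446 replicate 2 or romidepsin replicate 3. Thioredoxin, glutathione and NRF2 target genes were lower in 22 of 32 (median -0.08, camera adjusted p = 0.0365). They were not called without chaetocin replicate 1 (-0.08, 0.0569), F5446 replicate 2 (-0.06, 0.0568) or 3 (-0.05, 0.336), or romidepsin replicate 1 (-0.08, 0.0844), 2 (-0.06, 0.322) or 4 (-0.10, 0.0551). Neuronal genes were higher in 9 of 17 (median 0.15, camera adjusted p = 0.0365). They were not called without F5446 replicate 2 (0.17, 0.396) or 3 (0.26, 0.0512) or romidepsin replicate 1 (0.14, 0.0595), 2 (0.09, 0.132) or 3 (0.04, 0.160), and their median was 0.25 without F5446 replicate 4 and 0.26 without romidepsin replicate 4. With an estimated correlation the adjusted p of these 5 groups lay between 0.418 and 0.709. Metallothioneins (4 tested genes) had a median of -0.77 (camera adjusted p = 0.00145), and -0.46 without F5446 replicate 4 (0.110). Ribosomal proteins had one of -0.15, and -0.03 without F5446 replicate 2 (camera adjusted p = 0.443) and -0.10 without romidepsin replicate 1. Oxidative phosphorylation genes had one of -0.10, with the call lost without F5446 replicate 2 (0.02, camera adjusted p = 0.873) or romidepsin replicate 1 (-0.07, 0.135), and -0.16, -0.18 and -0.17 without F5446 replicate 3, F5446 replicate 4 or romidepsin replicate 3.

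Comparisons against DMSO share their control libraries, which alone makes their fold changes correlate. Across the tested genes, which are not independent replicates, Pearson's r between log2 fold changes was 0.721 for chaetocin and F5446, 0.738 for chaetocin and romidepsin and 0.722 for F5446 and romidepsin. Simulated groups with no treatment effect, with controls shared in the same way, gave 0.676, 0.715 and 0.675. Among genes with a mean of at least 10 CPM the values were 0.558, 0.520 and 0.544, below the simulated 0.634, 0.668 and 0.634. The simulation drew every library independently, the controls included, and held no structure by replicate number. Its differences from the observed values are therefore not read as more or less shared effect. With 0 genes called against DMSO by edgeR there were no calls to overlap. The median SE of a log2 fold change over these more abundant genes was 0.19 for chaetocin, 0.20 for F5446 and 0.19 for romidepsin against DMSO.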

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

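Of the tests here, those of single chaetocin libraries, of balanced splits, of too few libraries, swapped labels and exposure for the genes that HDAC inhibitors induce, and of library complexity were chosen after related results had been seen. The test of all splits with an estimated correlation was added after the real counts were known but before the splits were run.

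Antigen presentation and cytotoxic effector genes were lower with chaetocin than with romidepsin and than with F5446 (medians -0.21 and -0.29, the latter -0.44 without chaetocin replicate 4). Between romidepsin and F5446 camera with the preset correlation called antigen presentation higher with romidepsin. That call was lost without F5446 replicate 3 (camera adjusted p = 0.0512) or romidepsin replicate 3 (0.151). With an estimated correlation camera called neither list between romidepsin and F5446 (adjusted p = 0.469 and 0.709). Without any 1 chaetocin library the medians of romidepsin against chaetocin stayed at 0.28 to 0.36 (antigen presentation) and 0.23 to 0.42 (cytotoxic effectors). This argues against 1 chaetocin library as the sole source, though the cytotoxic median fell from 0.46 to 0.23 without chaetocin replicate 1 and to 0.29 without replicate 2. The largest camera adjusted p over both lists in these fits was 1.485e-05. That value used the preset correlation, which also called lists in other splits, and the estimated correlation was not tested in these fits. Replicate numbers 1 and 2 against 3 and 4 are balanced between these groups, so that division alone does not set the groups apart, and GC content or length of the members is argued against (at least 99.2% of the medians kept after both trends were removed). With an estimated correlation 2 lists were called in each of the 2 comparisons, which share the chaetocin libraries and so are not independent. In each this was reached by 1 of 35 splits, the real one (highest other 1). Unbalanced splits also carry the structure by replicate number, so this share does not exclude chance. The splits balanced over these numbers like the real one are 18 (highest other 1 against romidepsin and 0 against F5446), too few for a share under 0.05. Against the 2 DMSO libraries camera with the preset correlation called cytotoxic effectors lower with chaetocin (median -0.18, adjusted p = 0.000895, and -0.10, -0.28 and -0.39 without chaetocin replicate 1, 2 or 4) but not with romidepsin (0.25, 0.285), and antigen presentation higher with romidepsin (0.17, lost without DMSO replicate 4 at 0.0753) but not lower with chaetocin (-0.14, 0.103), and an estimated correlation called none of these (lowest 0.329), so an effect of chaetocin is a hypothesis, and an effect of romidepsin and a difference in handling that the labels do not record stay open.

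The genes that HDAC inhibitors commonly induce were not called higher with romidepsin than with DMSO, singly or as a list. Too few libraries is argued against for the more abundant members, since 9 of the 10 (90%) with a mean of at least 5 CPM had an interval below a 2-fold rise. CLU was the exception, and low members such as CDKN1A stay open. A swap of all labels with chaetocin is argued against for a 2-fold response, since 9 of 9 such members had an interval below a 2-fold rise there. With F5446 it was 8 of 10 (80%). For a swap with DMSO, 7 of 10 (70%) had an interval above a 2-fold fall with romidepsin. The cut chosen after related results were seen lies between these shares and argued against the swap with F5446 only. The shares rest on few genes, so neither of these swaps can be told apart. Nor can an exposure lower than labelled (list median 0.0541), which was not recorded, and single wrong labels were not tested. A response that had passed by 72 h is a biological explanation that was not tested.

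Chaetocin replicate 3 stood apart from the other libraries. GC content and transcript length are argued against, since its deviation from the other chaetocin libraries correlated across genes at r = 0.07 with GC content and -0.0893 with log transcript length. Lower complexity is a candidate explanation: thinned to the smallest total it had 16057 genes with a count, where the other libraries had 17332 to 20852. At 10 counts or more, without thinning, it had 14750 genes. The other libraries had 14613 (F5446 replicate 4) to 16104 (chaetocin replicate 2), so the deficit was not seen at that cut. Why fewer genes had any count was not tested, and the treatment is shared with 3 libraries that did not show it.

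Single libraries lay far from the rest of their group in 9 of 148 sets of values, where chance would give about 1 in 20, or 7.4. Only the chaetocin and romidepsin groups were tested in this way. The first-component score, mitochondrial share and number of detected genes of chaetocin replicate 3 were among the sets and did not pass this cut. GZMB was at 0.4665 CPM in chaetocin replicate 4 (others 0 to 0.0435) and at 0.7162 in romidepsin replicate 1 (others 0), both near the floor. In romidepsin replicate 1 TWIST1 was at 6.804 CPM (others 12.9 to 13.6) and SUV39H2 at 47.63 (others 33.7 to 34.9). In chaetocin replicate 3 HDAC2 was at 207.7 CPM (others 175.3 to 178.5) and KIR3DL2, which has near-identical relatives, at 388.4 (others 253.2 to 272.4). GBP2 was at 12.75 CPM in chaetocin replicate 4 (others 15 to 15.2). In romidepsin replicate 4 the score of interferon-stimulated genes was -0.1962 (others 0.16 to 0.23) and that of fibroblast markers 0.3175 (others -0.11 to -0.07).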

How the results depend on the processing

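The term for replicate numbers 1 and 2 against 3 and 4 (replicate-number term) and the 10 CPM minimum were chosen after the data were seen. Named genes stayed on their side of the threshold in 2541 of their alternatives, 79 lost a call and 43 gained 1. No called gene changed sign, but values of uncalled genes near 0 did, as for SUV39H1 with chaetocin (-0.10 to 0.15). The 4 list results held with an estimated correlation (cytotoxic effectors and antigen presentation, chaetocin against F5446 and romidepsin against chaetocin) kept their calls in all 19 alternatives. The estimated correlation was itself 1 of these alternatives and the ground for choosing the 4 results. The others except fry used the preset correlation, which also called lists in other splits. Some of them left out a library of a group not compared, so the 19 are weak support. In data simulated with 200 changed genes, 2-fold changes of genes of at least 5 CPM were found in 72% (chaetocin), 66% (F5446) and 66% (romidepsin) against DMSO. For 1.5-fold changes the shares were 12, 18 and 22%, so smaller changes were often missed. Whether these shares hold for the real libraries, with their structure by replicate number, was not tested. In the real fit ATF5 with chaetocin (2.76-fold, edgeR adjusted p = 0.299) and CKB with romidepsin (2.24-fold, 0.255) were not called against DMSO. The shares therefore do not exclude 2-fold effects among uncalled genes. Where a count moved, the cause was not tested. In all comparisons but romidepsin against chaetocin (939), 424 to 703 genes had an unadjusted edgeR p under 0.05, where 863 would by chance. With the replicate-number term chaetocin, F5446 and romidepsin against DMSO had 1157, 690 and 833 such genes. Chaetocin against F5446 had 974 and romidepsin against F5446 had 663. Part of the shortfall therefore went with the structure by replicate number, which the main fit does not model. Some counts stayed under 863, and the cause of the rest was not tested. Counts of 0 do not show an absence of effects.

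Counts of called genes, in the order chaetocin, F5446 and romidepsin against DMSO, chaetocin against F5446, romidepsin against chaetocin and romidepsin against F5446, were 0, 0, 0, 0, 16 and 0. With DESeq2 they were 10, 1, 1, 2, 62 and 0. Without the filter they were 9, 0, 5, 9, 72 and 6. With the replicate-number term they were 7, 0, 1, 5, 108 and 0. A fit of the compared groups alone gave 7 for romidepsin against chaetocin and 2 against F5446, a minimum log2 fold of 0.5 gave 0 for the former, and a fit without robust estimation gave 1 for chaetocin against DMSO. With single libraries left out, counts ran from 0 to 2 for chaetocin against DMSO and from 5 to 22 for romidepsin against chaetocin, and stayed at 0 in the others.

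Counts of called lists, in the same order, were 6, 4, 2, 10, 12 and 11. With an estimated correlation they were 0, 0, 0, 2, 2 and 0, and with fry, which asks another question, 0, 0, 0, 2, 3 and 0. With single libraries left out they ran from 5 to 8, 2 to 9, 2 to 7, 5 to 13, 6 to 18 and 4 to 11. In that setting 7 list results changed the sign of their median or test and lost their calls: mitochondrially encoded genes, F5446 against DMSO (0.043 without DMSO replicate 1), the stress response, romidepsin against chaetocin (0.0017 without chaetocin replicate 3), ribosomal proteins, F5446 against DMSO (0.0246 without DMSO replicate 4, range -0.0069 without F5446 replicate 2 to 0.2066), glycolysis, romidepsin against DMSO (-0.3953 to 0.1574, the latter without DMSO replicate 4) and chaetocin against F5446 (-0.4272 to 0.0341, the latter without F5446 replicate 4), and oxidative phosphorylation, chaetocin against F5446 (-0.0311 without chaetocin replicate 3, highest 0.2263) and romidepsin against F5446 (-0.1818 to 0.0192, the latter without F5446 replicate 2). The correlations of fold changes ran from 0.7998 to 0.8226 (chaetocin and F5446), 0.7932 to 0.8247 (chaetocin and romidepsin) and 0.8031 to 0.8366 (F5446 and romidepsin) with 1 DMSO library left out, since a single control is then shared; over genes of at least 10 CPM they were 0.5581, 0.52 and 0.5444.

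Replicate numbers were tested as a block. In 15 pairs of libraries with the same number, residuals correlated at 0.036 to 0.222 (median 0.106), with 8 above 0.1. In 47 pairs with different numbers they correlated at -0.192 to 0.185 (median -0.068), with 5 above 0.1. These 5 lay within numbers 1 and 2 or within 3 and 4, where all such pairs were positive. Pairs across these sets were all negative, so the residuals also followed the sets. Centering within groups forces mirrored values, as for chaetocin replicate 1 with DMSO replicates 1 (0.162) and 4 (-0.162). The negative median is therefore no baseline for pairing. Of 13 libraries, 10 correlated best with one of their own number. The rule set for pairing was not met, so the block stayed an alternative, but these values do not show that the replicates are unpaired. With the block the gene counts were 10, 0, 1, 11, 144 and 2 (the last CAPN6 and CKB, edgeR adjusted p = 0.0133 and 0.01002). The list counts were 8, 2, 4, 11, 13 and 11. Of the list calls of the main fit, 4 of 6, 2 of 4, 2 of 2, 9 of 10, 11 of 12 and 10 of 11 were kept. Ribosomal proteins with F5446 against DMSO were at -0.053, and the correlation for F5446 and romidepsin was 0.7406.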

Other observations

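Tests of other splits with an estimated correlation were added after the real counts were known, but before the splits were run, and those with a term for replicate numbers were limited to balanced splits after all counts were known. With a term for replicate numbers 1 and 2 against 3 and 4, further genes were called between romidepsin and chaetocin, and those named here were chosen after their values were seen, so they show no theme of the whole. Higher with romidepsin were the chemokine receptors CCR1 (log2 difference 0.80) and CCR2 (1.06) and the interleukin receptor subunit IL2RB (0.73), and the guanylate-binding proteins GBP1 (0.64), GBP5 (0.53) and GBP6 (2.30), which interferon induces, and HLA-B (0.69) and HLA-E (0.67), whose counts depend on reads shared between near-identical genes. TNFRSF18, a costimulatory receptor related to TNFRSF4, was lower (-1.11).

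Other splits of the same libraries were counted. Of 35 splits of the romidepsin and chaetocin libraries, 2 gave at least 16 genes, and the highest other, 545, followed replicate numbers 1 and 2 against 3 and 4, which points to a structure of the samples. For the 16 genes chance cannot be excluded over these splits. Among the 18 splits balanced over the replicate numbers only the real one reached 16 (highest other 0), but 18 are too few for a share under 0.05. With a term for these numbers only the 18 splits balanced over them like the real one were compared, too few for a share under 0.05: the real split gave 108 genes, reached by 1 of 18 (highest other 0). For the 12 lists 6 of 35 splits gave as many (highest other 15), so chance cannot be excluded. Between chaetocin and F5446 the real count of 0 genes is reached by all 35 splits by construction and tests nothing. The split that follows replicate numbers gave 137 genes, the highest, again a structure of the samples. With the term 2 of the 18 balanced splits gave at least the real 5 genes (highest other 15). Without it 6 of 35 gave at least the real 10 lists (highest other 12), so chance cannot be excluded for the lists. Between romidepsin and F5446 chance cannot be excluded for the 11 lists (10 of 35 splits, highest other 17), and the split that follows replicate numbers gave 12. For 0 genes (highest other 2) and 0 lists with an estimated correlation (highest other 0) all 35 splits must reach the real count, as must all 18 for 0 genes with the term (highest other 0), which says nothing about chance.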
